A study of Mus musculus with 9 samples.

How the data were processed

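The series measured total RNA from a clonal line of mesenchymal stromal cells, named MSC2, grown from the bone marrow of 6-week-old C57BL/6 mice, with 9 biotin-labelled expression arrays. Undifferentiated cells, cells induced toward osteoblasts for 14 days and cells induced for 28 days have 3 arrays each, which the series text calls independent replicates. Per the labels' protocols, undifferentiated cells grew in alpha-MEM free of ascorbic acid, and confluent cells were induced in DMEM with 0.1 µM dexamethasone, 0.2 mM ascorbate phosphate, 10 mM beta-glycerophosphate and 1 mM pyruvate. Both media held 10% serum. The mean RNA integrity number was 9.9, per the labels. Induced and undifferentiated cultures thus differ in medium, confluence and time as well as in induction, and no uninduced culture of the same age is among the samples.

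The submitters' processing notes name RMA as the method behind the deposited log2 values. Its software, version and annotation are not given in the sources used here. The log base is not written with the values and is taken as 2 because RMA works in log2. Each of the 33794 probe sets has a median of 0 over the 9 arrays, so every probe set was centred on its own median and no absolute level is kept. The step that did this is not given in the sources used here. The median of each array is 0 as well. The scale of the values is known only through RMA, the centring is read from the values, and the direction (a higher value for more RNA) is assumed and was checked only by genes with a known response to dexamethasone, such as Fkbp5. Values run from -6.33 to 3.42. For arrays, their number limits the precision.

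Probe sets were paired with genes through the annotation table supplied with the values. Of the 33794 probe sets, 23521 have 1 gene, 1814 have several and 8459 have none. Those with 1 gene were used, and 23328 of them matched a RefSeq gene of assembly GRCm38.p6 by Entrez number, with 0 symbols changed. The 10273 probe sets with no gene or several were left out of the comparisons. A gene with several probe sets took their mean, which gave 22180 genes, 21098 of them with 1 probe set. The design had named the probe set with the highest mean, but centred values have no level to rank, so the mean over probe sets, listed beforehand as the other choice, was used. In 33 genes the probe sets disagreed in the direction of a call. No coordinates were used.

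Many values tie, and 15.2% to 28.1% of the values of an array are exactly 0. In 873 genes (3.94%) the 3 arrays of a group hold the same value, most often at 14 days with 446 genes, so the spread of such a group is understated. Of the genes with such ties, 9.97% were called at 14 days, against 36.8% of the genes without.

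Differences were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated variances (6 residual and 3.81 prior degrees of freedom), and p-values were adjusted by the Benjamini-Hochberg method over the 22180 genes in each comparison. A gene was called at an adjusted p under 0.05. The 3 comparisons are 14 days minus undifferentiated, 28 days minus undifferentiated and 28 days minus 14 days, and an F test asked which genes differ among the 3 groups. Standard errors come from the fit, and standard deviations (SD) from the 3 arrays of a group.

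Before the data were examined, 33 gene lists were fixed for the bone, matrix, stromal, signalling, metabolic and other-cell genes that the cultures could hold. Each was tested against all other genes with limma's camera at a preset correlation of 0.01, and again with the correlation estimated for each list, with adjustment over the 33 lists. All 33 have at least 5 measured members. The genes named in the text follow a rule fixed at the same time. Per comparison it takes the 10 largest rises and the 10 largest falls among called genes whose arrays do not overlap, leaving out gene-model, clone and small-RNA names. Per list and comparison it takes up to 4 called members with the largest change. It always takes Sp7, Alpl, Bglap, Ibsp, Col1a1, Dmp1, Sost, Pparg, Fabp4, Sox9, Mki67, Fkbp5, Tnfsf11 and Tnfrsf11b. Runx2 and Spp1 were on that rule too and were not analysed here. Not every gene that the rule allows is printed.

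The comparisons with undifferentiated cells share their control arrays, so 20 simulated sets of unchanged groups against the same controls gave the overlap and correlation that sharing alone produces. The steps were tested on simulated data with 200 changed genes among 22180 for the comparison at 14 days. The fit recovered 82% of the genes changed 1.25-fold and 100% of those changed 1.5-fold, 2-fold or 4-fold, and 3.54% of its 198 calls were false. In 20 runs with no change, 0 of the 33 lists were called. Genes were simulated independently of each other, so these runs cannot show how often lists of correlated genes are called by chance. In the real arrays the estimated correlation reached 0.17, for the glucocorticoid-responsive list.

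The alternatives tried were a replicate block, quantile normalization again, array weights, fits on only the groups compared, limma's treat against a 1.5-fold change, an adjusted p under 0.01, limma's fry, and each array left out in turn. Quantile normalization again was run on the centred values, so it does not repeat the normalization of RMA. The SD of an array was 0.401 to 0.41 in undifferentiated cells, 0.089 to 0.124 at 14 days and 0.15 to 0.166 at 28 days. Forcing equal spread on such arrays can itself move counts, medians and calls. It tends to lower changes against undifferentiated cells and to raise those between 14 and 28 days. Added after the data were seen were robust variance moderation, only genes with 1 probe set, each probe set on its own, genes with tied groups left out, and 5 further gene lists.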

Results

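Gene expression was compared among 3 states of MSC2, a clonal line of stromal cells from mouse bone marrow: undifferentiated cells, cells after 14 days and cells after 28 days of osteoblastic induction, with 3 arrays in each group. The values are log2 signals centred on each gene's median over the 9 arrays, so they compare groups and give no level of a gene. The table holds 33794 probe sets, and 22180 genes were compared. In a principal component analysis, the first component held 87.1% of the variance and placed undifferentiated arrays at -49.58 to -48.22, 14-day arrays at 17.91 to 18.92 and 28-day arrays at 29.94 to 30.86. The SD of the gene-wise difference between arrays of the same group averaged 0.128 over 9 pairs. It averaged 0.47 between undifferentiated and 14-day arrays, 0.547 between undifferentiated and 28-day arrays and 0.18 between 14-day and 28-day arrays. An F test in limma found 8704 genes that differed among the 3 groups at an adjusted p under 0.05.

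The comparison of 14 days with undifferentiated cells asks what the induction medium and its time course had changed midway. Genes of cell division fell together: all 38 measured members of the cell cycle list fell, with a median log2 fold change of -1.77 (-0.94 after quantile normalization again), and Mki67, a marker of dividing cells (probe set 17497334), went from 1.95 ± 0.02 to -0.02 ± 0.04 (SD, n = 3), a log2 fold change of -1.97 (SE 0.04, limma adjusted p = 1.84e-10). Of 25 genes that answer glucocorticoids 18 rose (camera adjusted p = 8.14e-10, and adjusted p = 0.12 with an estimated correlation), with Fkbp5, a chaperone of the glucocorticoid receptor, up 2.67-fold (log2 1.42, SE 0.06, limma adjusted p = 2.15e-08). Lysosomal genes rose in 20 of 21 members. Of the bone genes, Alpl, the alkaline phosphatase of mineralizing cells, rose 1.41-fold, while Sp7, Ibsp, Bglap and Dmp1 did not pass the test.

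In total 7920 genes (35.7%) changed at 14 days, 4040 up and 3880 down, and 1045 of them changed at least 2-fold. After quantile normalization again 317 genes changed at least 2-fold, and in the test against a 1.5-fold change 1582 genes were called. The largest rise was that of Fmo2, a flavin monooxygenase (probe set 17229036), from -6.16 ± 0.22 to -0.003 ± 0.008 (SD, n = 3), which is 71.5-fold (SE 0.09 on the log2 scale, limma adjusted p = 4.71e-11). Next came Itgbl1 with 33.7-fold, the melanocyte antigen gene Mlana with 24.5-fold and Ptgds, which encodes a prostaglandin D synthase, with 23.1-fold. Wfdc1, Mamdc2, Angptl7, Chil1, Lamc3 and Aspn, which encodes the matrix protein asporin, rose between 17.6-fold and 19.6-fold. The largest fall was that of Has2, a hyaluronan synthase (probe set 17317167), from 3.39 ± 0.04 to -0.08 ± 0.22, a log2 fold change of -3.46 (SE 0.10, limma adjusted p = 1.41e-09). Tnfsf18 with -3.29, Ankrd1 with -2.86, Igf1, which encodes insulin-like growth factor 1, with -2.76 and Cth with -2.74 followed. H1f5 and H2bc12 also fell, and as histone genes with close copies their values are uncertain.

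**Figure D1:**
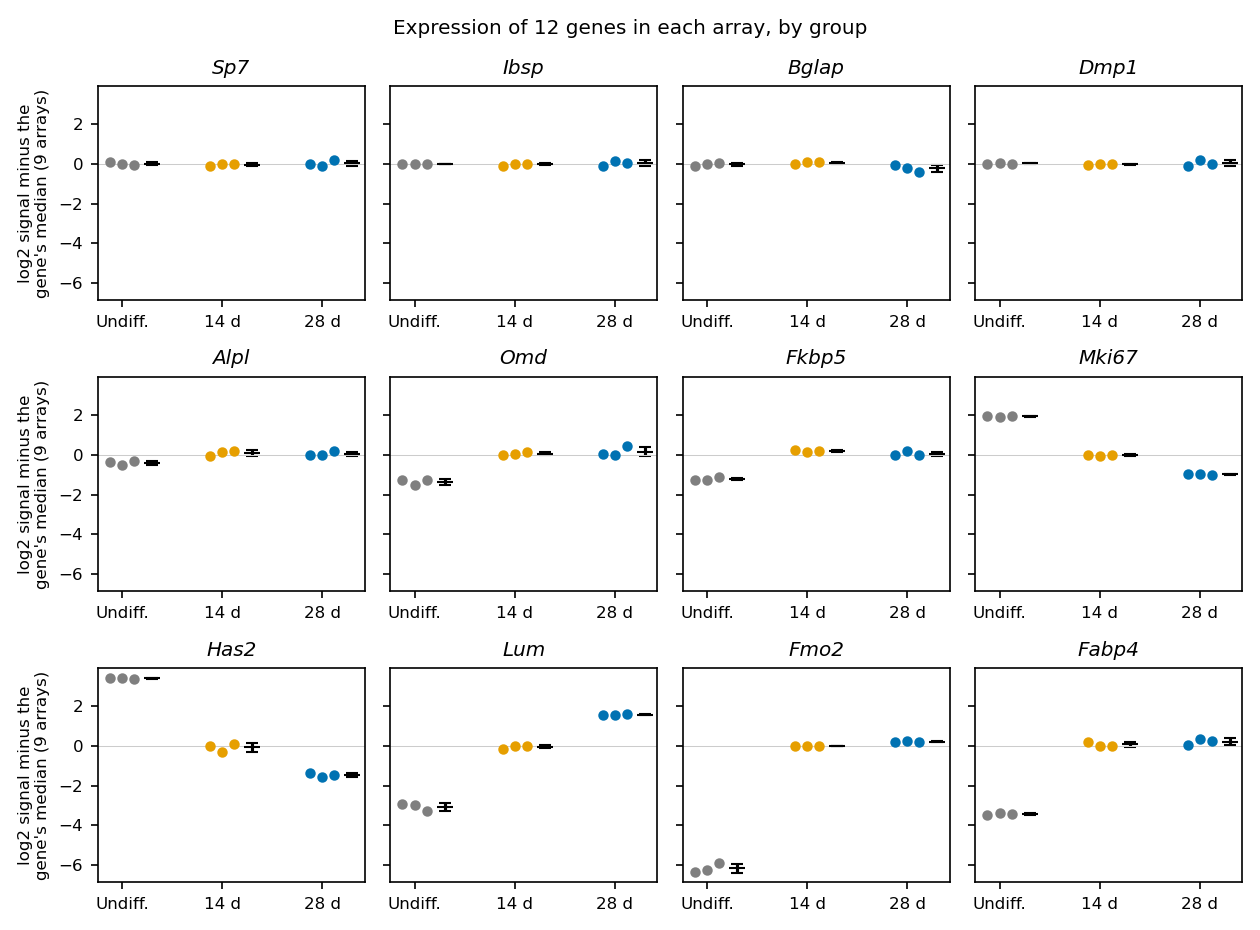
Log2 signal minus the gene's median over the 9 arrays (vertical axis) for 12 genes in undifferentiated, 14-day and 28-day cultures; points are single arrays, and bars give the group mean and SD (n = 3). Sp7, Ibsp, Bglap and Dmp1 stay near 0 in all groups, Mki67 steps down from 1.95 to -0.97, and Fmo2 rises from -6.16.

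Of the 33 gene lists, camera called 11 at 14 days, 8 up and 3 down, and 3 hold with an estimated correlation: cell cycle, lysosome, and contractile and serum response factor targets. The cell cycle list (camera adjusted p = 1.46e-32, and adjusted p = 0.0092 with an estimated correlation) fell in 38 of 38 members, and in 38 adjusted over the list alone, with Plk1 at -2.25 and Cdc20 at -2.19. The lysosome list (4.51e-14, and adjusted p = 0.0092 with an estimated correlation) had 20 members up and 0 down, the same counts adjusted over the list alone, among them the cathepsin genes Ctsf at 2.22 and Ctsl at 1.26 and the glycosidase genes Gla at 1.59 and Neu1 at 1.55. Of 22 contractile genes, 18 fell and 3 rose, and the same numbers were adjusted over the list alone (camera adjusted p = 8.47e-08, and adjusted p = 0.045 with an estimated correlation), with the smooth muscle genes Actg2 at -2.38 and Cnn1 at -1.99.

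The glucocorticoid list had 18 of 25 members up and 0 down, and 19 up and 1 down adjusted over the list alone (camera adjusted p = 8.14e-10, and adjusted p = 0.12 with an estimated correlation). Its largest rises were Hsd11b1, which encodes the enzyme that regenerates active glucocorticoid, at 2.94, the metallothionein gene Mt2 at 2.75, Sult1a1 at 2.47 and Klf9 at 1.80. In the complement list 8 of 14 members rose and 2 fell, as also adjusted over the list alone (0.00286, and adjusted p = 0.12 with an estimated correlation), with C2 at 2.21, Cfb at 2.11 and Cfi at 1.89. In the mineral and phosphate list 7 of 12 rose and 1 fell, or 7 and 2 adjusted over the list alone (0.0148, and adjusted p = 0.12 with an estimated correlation). They include Car12 at 1.86, the pyrophosphate transporter gene Ank at 1.55, Mgp, an inhibitor of calcification, at 1.52 and Smpd3 at 1.12.

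Small leucine-rich and other matrix proteins rose in 15 of 28 members and fell in 8, or 16 and 9 adjusted over the list alone (0.0148, and adjusted p = 0.19 with an estimated correlation). Thbs2 rose by 3.28 and Lum by 3.03, while Tnc fell by 2.20 on the log2 scale. The glycolysis and hypoxia list (camera adjusted p = 0.0148, and adjusted p = 0.32 with an estimated correlation) had 11 of 22 members up and 3 down, with Egln3, an oxygen sensor, at 2.81 and Eno2 at 1.76. Of the niche factors that stromal cells offer to blood progenitors, 10 of 21 fell and 2 rose (0.0212, and adjusted p = 0.12 with an estimated correlation). Jag1 was at -1.90 and Csf1 at -1.86, and Il34, which shares its receptor with Csf1, rose by 1.68. The adipocyte list (0.0279, and adjusted p = 0.2 with an estimated correlation) had 8 of 21 members up and 1 down, led by the fatty acid carrier gene Fabp4 at 3.50, while Pparg stood at -0.04 (SE 0.06). The adipocyte call was lost without day-14 replicate 2 (0.0518) and after quantile normalization again (0.0712), in a range of 8.94e-06 to 0.204 over the alternatives. For the glycolysis, niche and adipocyte lists the counts adjusted over the list alone were the same.

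The osteoblast list had 4 of 18 measured members up and 1 down, as also adjusted over the list alone, and was not called (camera adjusted p = 0.464). Omd, which encodes osteomodulin, rose by 1.42 and Pth1r, the parathyroid hormone receptor gene, by 0.66. Alpl rose by 0.50 (SE 0.09, limma adjusted p = 0.000896), a call lost when quantile normalization again forced equal spread on the centred arrays (adjusted p = 0.104). Over all alternatives its adjusted p ran from 0.000302 to 1, the latter in the test against a 1.5-fold change. Col1a1 was at -0.26 (SE 0.04, limma adjusted p = 0.000708). Log2 fold changes were -0.05 for Sp7, -0.04 for Ibsp, 0.09 for Bglap, -0.04 for Dmp1, -0.01 for Sost and -0.03 for Tnfsf11, with limma adjusted p-values of 0.673, 0.747, 0.47, 0.691, 0.954 and 0.778. Sox9 rose by 0.94, and the chondrocyte list had 4 of 20 members up (camera adjusted p = 0.189). Runx2 and Spp1 were not analysed here.

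Markers of other cell types moved in part. In the macrophage list 4 of 16 rose and 0 fell, led by Cd14 at 2.56 and Csf1r at 1.81, and the list was not called (0.229), with a median of -0.002, a mean of 0.32 and a test direction of up. The endothelial list was called (0.0148, and adjusted p = 0.14 with an estimated correlation) with 6 of 14 up and 0 down, as also adjusted over the list alone, led by Kdr at 1.91 and Erg at 1.18. The osteoclast, blood, muscle, and epithelial and neural lists were not called, with adjusted p-values of 0.965, 0.771, 0.564 and 0.418. Also not called were collagen chains, with 8 of 24 up and 6 down, Notch pathway genes, with 2 of 17 up and 7 down, and oxidative phosphorylation genes, with 3 of 28 up and 10 down. Median, mean and test differed in sign for BMP and TGF-beta genes (median 0.01, mean -0.15, test down), antioxidant genes (-0.006, 0.015, down) and osteoclast genes (-0.01, 0.06, down). Arrays of both groups did not overlap in 7828 of the called genes. Over all genes 44.8% did not overlap, against 10% by chance.

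The comparison of 28 days with undifferentiated cells asks what the longer induction had changed. Cell division genes lay lower still: all 38 fell, with a median of -2.32, and Mki67 was at -2.92 (SE 0.04, limma adjusted p = 1.44e-11). Of 28 matrix genes 17 rose and 8 fell, and of 14 complement genes 8 rose and 2 fell (adjusted p = 0.18 and adjusted p = 0.16 with an estimated correlation). Lum, which encodes the collagen-binding lumican (probe set 17236811), rose 25.1-fold from -3.08 ± 0.20 to 1.57 ± 0.004 (SD, n = 3), and C4b rose 7.67-fold. Of the bone genes, 4 stayed without a call: log2 fold changes were 0.02 for Sp7, 0.03 for Ibsp, -0.18 for Bglap and 0.01 for Dmp1, and their 95% intervals reached no higher than 0.18.

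In all, 8845 genes (39.9%) changed at 28 days, 4526 up and 4319 down, 1373 of them at least 2-fold. After quantile normalization again 5729 genes were called, 2680 of them up, and 689 changed at least 2-fold. In the test against a 1.5-fold change 2010 were called. Fmo2 again rose most with 83-fold (log2 6.38, SE 0.09, limma adjusted p = 1.8e-11), followed by Itgbl1 with 45.7-fold, Chil1 with 35-fold, Lamc3 with 30.1-fold and Wfdc1 with 29.7-fold. Thbs2, which encodes thrombospondin 2, rose 28.9-fold. Has2 fell most with -4.86 (SE 0.10, limma adjusted p = 8.78e-11), followed by the adhesion receptor gene Adgrg6 with -3.52, Cth with -3.45 and the mitotic kinesin gene Kif23 with -3.40. Arrays of both groups did not overlap in 8659 of the called genes. Over all genes 46.6% did not overlap, against 10% by chance.

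Camera called 10 lists at 28 days, 8 up and 2 down, and 2 hold with an estimated correlation, cell cycle and lysosome. The cell cycle list (camera adjusted p = 3.34e-34, and adjusted p = 0.011 with an estimated correlation) includes Bub1 at -3.29, Plk1 at -3.25 and Cenpe at -3.11. The lysosome list had 20 of 21 up and 1 down (4.97e-11, and adjusted p = 0.018 with an estimated correlation), with Ctsf at 2.53 and Neu1 at 1.49. The glucocorticoid list had 21 of 25 up and 1 down (8.82e-11, and adjusted p = 0.13 with an estimated correlation), with Hsd11b1 at 3.27, Glul at 1.90 and Fkbp5 at 1.27. Contractile genes fell in 17 of 22 and rose in 3, or 18 and 3 adjusted over the list alone (2.01e-06, and adjusted p = 0.074 with an estimated correlation). Actg2 was at -2.77 and Ankrd1 at -3.37. The counts adjusted over the list alone equal those over all genes for the cell cycle, lysosome, glucocorticoid, complement, adipocyte and mineral lists.

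Complement genes rose in 8 of 14 and fell in 2 (camera adjusted p = 0.00286, and adjusted p = 0.16 with an estimated correlation), with C2 at 3.44, C4b at 2.94 and Cfi at 2.75. Small leucine-rich and other matrix proteins rose in 17 of 28 and fell in 8, or 18 and 8 adjusted over the list alone (0.0129, and adjusted p = 0.18 with an estimated correlation), with Thbs2 at 4.86, Lum at 4.65 and the elastin gene Eln at 2.85. The adipocyte list rose in 9 of 21 and fell in 1 (0.014, and adjusted p = 0.18 with an estimated correlation), with Fabp4 at 3.63 and Pparg at -0.07. The endothelial list rose in 9 of 14 and fell in 0, or 9 and 1 adjusted over the list alone (0.0218, and adjusted p = 0.18 with an estimated correlation), with Kdr at 1.91. Mineral genes rose in 7 of 12 and fell in 3 (0.0375, and adjusted p = 0.18 with an estimated correlation), with Car12 at 2.46 and Mgp at 1.61. The glycolysis list rose in 11 of 22 and fell in 4, or 11 and 5 adjusted over the list alone (0.0481, and adjusted p = 0.38 with an estimated correlation), with Egln3 at 2.89. Its call was lost without undifferentiated replicate 3 (0.0538), day-14 replicate 1 (0.0576) or day-28 replicate 2 (0.0639), in a fit of the groups compared alone (0.0535) and on genes with 1 probe set (0.0766), in a range of 2.75e-06 to 0.382 over the alternatives.

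The osteoblast list had 5 of 18 members up and 1 down (camera adjusted p = 0.449), with Omd at 1.51, Pth1r at 1.03 and Alpl at 0.46 (SE 0.09, limma adjusted p = 0.0013). Its call was lost after quantile normalization again (adjusted p = 0.297, in a range of 0.000559 to 1 over the alternatives). Col1a1 was at -0.39. Sost was at -0.14 (SE 0.07, limma adjusted p = 0.12), Tnfsf11 at 0.05 and Tnfrsf11b at -0.01. The chondrocyte list had 7 of 20 up and 0 down (0.0816), with Prg4, which encodes the lubricant lubricin, at 3.69, Sox9 at 0.80 and Col10a1, a collagen of hypertrophic cartilage, at 0.77. Of the stromal progenitor markers 8 of 19 rose and 5 fell (0.386): Ctsk rose by 3.32 and Nt5e by 2.70, while Mcam was at -2.63 and Cd44 at -2.59. In the macrophage list Cd14 was at 2.75 and Csf1r at 2.10, and 4 of 16 rose (0.242). Median, mean and test differed in sign for osteoclast genes (median -0.01, mean 0.09, test down).

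**Figure D2:**
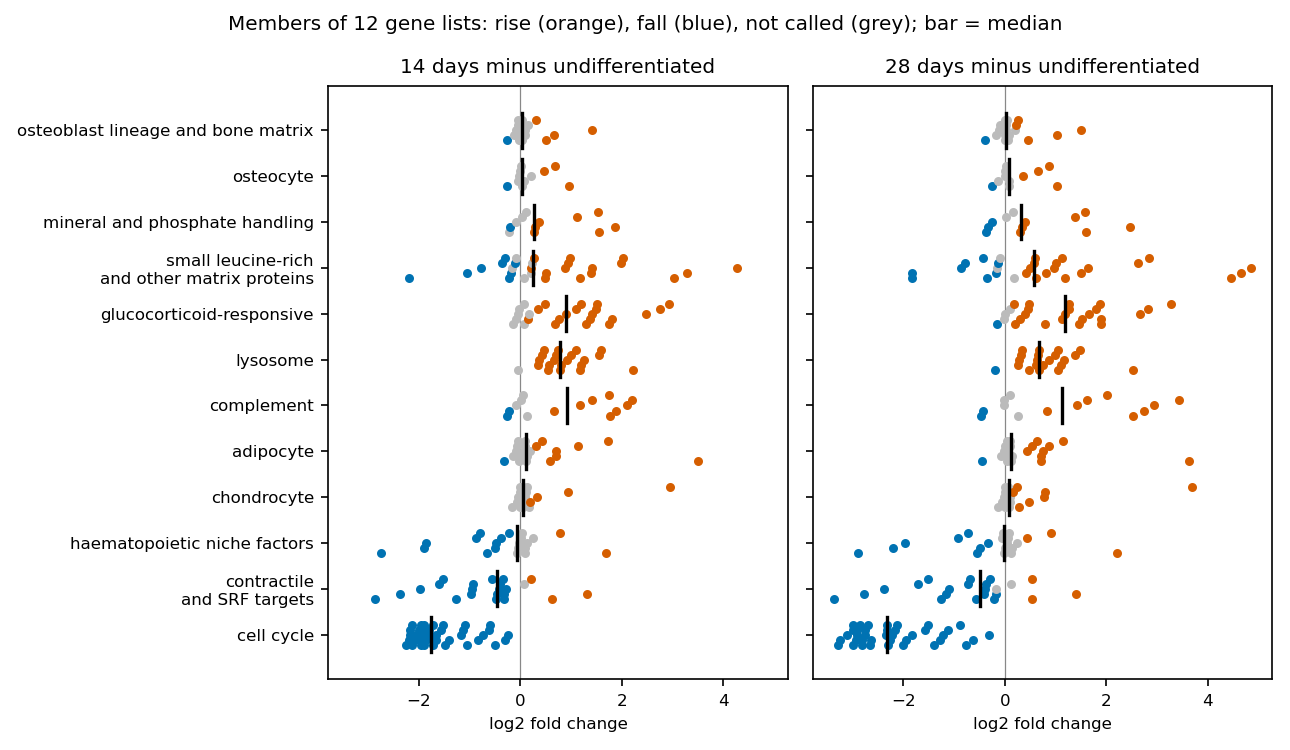
Log2 fold change of each measured member (points, horizontal axis) of 12 gene lists at 14 and at 28 days against undifferentiated cells (3 arrays per group); orange points rose, blue points fell, grey points were not called, and bars mark list medians. All 38 cell cycle genes lie left of 0 in both panels, 20 of 21 lysosome genes rose at each time, and most osteoblast genes sit near 0.

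Most genes called at 14 days were called again at 28 days. Of the genes called at 14 days, 7152 were called at 28 days too: 3607 rose and 3535 fell at both, and 10 changed in opposite directions. The overlap of independent lists would be 824.4 for rises and 755.5 for falls. Simulated arrays with no changed gene gave 0 same-direction calls, which the lack of any change fixes in advance. That count cannot show how much sharing the controls adds to the overlap. Log2 fold changes at 14 and 28 days correlated across genes (which are not independent replicates) at 0.967, against 0.5 from shared controls alone, and their covariance was 0.238 against 0.00228. Sharing alone thus makes up a small part of that covariance. It gives no count of calls, and the 3 control arrays could not be split into parts of at least 2. A part of the excess of calls over independent lists may therefore come from sharing them, and its size was not measured. After quantile normalization again, same-direction calls numbered 3833.

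The comparison of 28 with 14 days asks what changed late. Cell division genes fell further in 36 of 38 members, by a median of -0.66 (-1.07 after quantile normalization again), with Bub1 at -1.16 (SE 0.06, limma adjusted p = 6.89e-06) and Mki67 at -0.95 (SE 0.04, limma adjusted p = 3e-06). Lum rose a further 3.08-fold (log2 1.62, SE 0.09, limma adjusted p = 6.89e-06), Thbs2 2.97-fold and C4b 2.90-fold. None of the 18 osteoblast list members was called.

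Between 14 and 28 days 1639 genes (7.39%) changed, 603 up and 1036 down, and 24 changed at least 2-fold. Without day-14 replicate 1 the count was 991, without day-14 replicate 2 it was 1017, at an adjusted p under 0.01 it was 813, and in the test against a 1.5-fold change it was 28. After quantile normalization again 198 genes changed at least 2-fold. Pappa2, C2, Ctsk, which encodes cathepsin K, and Il17re rose by 1.26, 1.23, 1.21 and 1.19. Has2 fell by 1.39 (SE 0.10, limma adjusted p = 2.71e-05), and Adgrg6, Serpinb7, Kif23, Ndc80 and Nuf2 were at -1.18, -1.16, -1.14, -1.13 and -1.02. Erv3, an endogenous retroviral gene, fell by 1.06 after a rise of 2.70 at 14 days. All 1639 called genes had arrays of the groups that did not overlap, and over all genes 24.4% did not overlap, against 10% by chance.

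**Figure D3:**
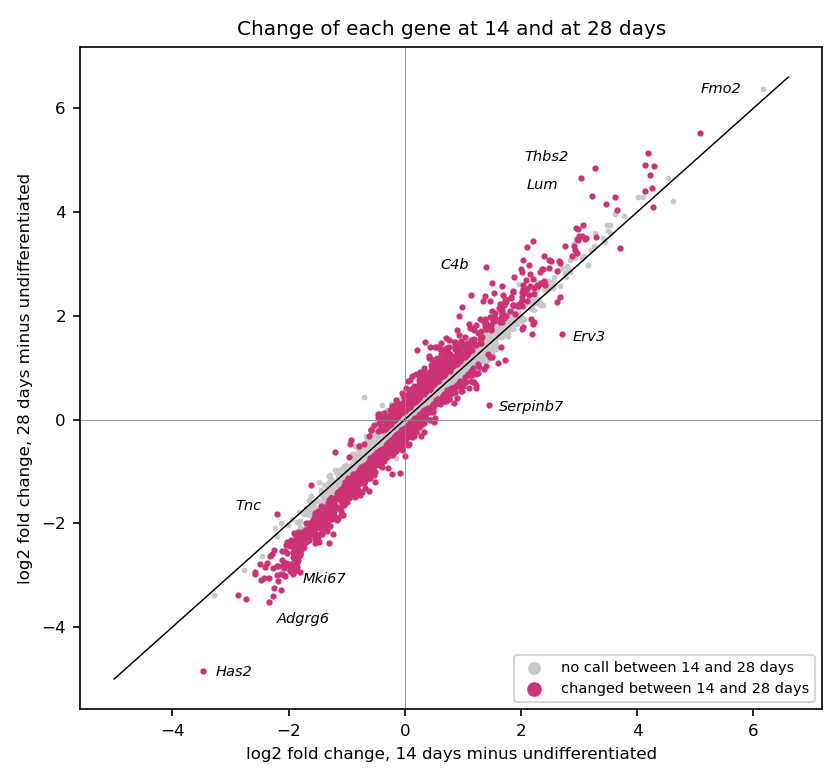
Log2 fold change against undifferentiated cells at 14 days (horizontal axis) and at 28 days (vertical axis) for each of the 22180 genes (3 arrays per group, a point per gene); coloured points changed between 14 and 28 days, and the diagonal marks equal change. Genes such as Lum, Thbs2 and C4b lie above the diagonal, and Has2, Adgrg6 and Mki67 lie below it.

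Camera called 8 lists between 14 and 28 days, 5 up and 3 down, and cell cycle alone holds with an estimated correlation (camera adjusted p = 4.52e-54, and adjusted p = 0.0031 with an estimated correlation); adjusted over the list alone, 37 of its members fell. Cholesterol synthesis genes fell in 8 of 18 and rose in 0, or 11 down adjusted over the list alone (4.8e-07, and adjusted p = 0.15 with an estimated correlation), with Hmgcs1 at -0.48 and Sqle at -0.46. Glucocorticoid genes rose in 7 of 25, or 10 adjusted over the list alone (4.8e-06, and adjusted p = 0.2 with an estimated correlation), with Lcn2 at 0.76 and Glul at 0.52. Wnt pathway genes rose in 6 of 33, or 9 adjusted over the list alone (0.000331, and adjusted p = 0.07 with an estimated correlation). The members named by the rule are the Wnt antagonist genes Sfrp1 at 0.63 and Frzb at 0.59, the inhibitor gene Nkd2 at 0.32 and the ligand gene Wnt5b at 0.30.

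Matrix proteins rose in 10 of 28 and fell in 4, or 14 and 6 adjusted over the list alone (0.000594, and adjusted p = 0.15 with an estimated correlation), with Eln at 0.83 and Fbn2 at -0.78. Immediate early genes rose in 6 of 17, or 7 up and 2 down adjusted over the list alone (0.00168, and adjusted p = 0.15 with an estimated correlation), with Egr1 at 0.55, Nr4a1 at 0.52 and Fos at 0.52. Complement genes rose in 5 of 14 and fell in 1, or 5 and 2 adjusted over the list alone (0.00299, and adjusted p = 0.15 with an estimated correlation). The lysosome list had 1 member up, Ctsf at 0.31, and 1 down, Mcoln1 at -0.19, as also adjusted over the list alone (0.0317, and adjusted p = 0.24 with an estimated correlation). Its call was lost without day-14 replicate 1 (0.0823) or day-28 replicate 2 (0.102), and on genes with 1 probe set (0.0577), in a range of 0.000402 to 0.243 over the alternatives. Median, mean and test differed in sign for matrix proteases (median -0.003, mean 0.005, test down) and for epithelial and neural genes (-0.01, 0.04, up).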

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

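Tests on compression by normalization, probe response, array scaling, time and medium, macrophages and endothelial cells were chosen only after the result was seen. The splits of the arrays were set beforehand. The list of YAP and TAZ targets was written after the first results were seen. Its test was set before the values of its unseen targets were seen. Groups of 3 arrays were not tested for a single array far from the others.

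Results that differ between 14 and 28 days by limma's or camera's test of the difference stand out first. Median log2 differences of the lists were -0.661 for cell cycle, -0.184 for cholesterol synthesis, -0.088 for lysosome, 0.166 for small leucine-rich and other matrix proteins, 0.159 for complement, 0.146 for immediate early and heat shock, 0.137 for glucocorticoid-responsive and 0.048 for Wnt pathway genes. After quantile normalization again, medians over 1.5 times as large were -1.071 for cell cycle, -0.361 for cholesterol synthesis, -0.161 for lysosome, 0.251 for matrix proteins, 0.252 for complement and 0.087 for Wnt genes. Matrix proteins gave 0.096 on genes with 1 probe set, Wnt genes 0.094 without day-28 replicate 1 and immediate early genes 0.094 without day-14 replicate 1. Of these 8 calls, cell cycle alone holds with an estimated correlation (adjusted p = 0.0031), and the others had an adjusted p of 0.07 (Wnt) to 0.24 (lysosome) with an estimated correlation. The lysosome call was also lost without day-14 replicate 1 (0.0823), without day-28 replicate 2 (0.102) and on genes with 1 probe set (0.0577), in a range of 0.000402 to 0.243 over the alternatives. Mki67 differed by -0.951. Of the 1384 genes called in both steps, 180 rose and then fell, and 63 fell and then rose, while 429 rose and 712 fell in both. The opposite-direction count of 243 became 630 after quantile normalization again and 70 at an adjusted p under 0.01, and leaving out 1 array gave 119 without day-14 replicate 1 (130 and 145 without replicates 2 and 3), 138 to 154 without a day-28 array and 205 to 216 without an undifferentiated array. Independent steps would give 294.2 genes of opposite direction and 291.1 of the same. The steps share the 14-day arrays, and their log2 changes correlated across genes (not independent replicates) at 0.397, against -0.5 simulated with no change, with a covariance of 0.027 against -0.00228. Outside the genes compared, 1643 of the 10273 probe sets with no gene or several (16%) differed among the 3 groups, against 39.2% of the genes used.

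The count of 8704 genes that differ among the 3 groups was reached by 1 of 100 splits of the 9 arrays, the real one, and the highest other split gave 10 genes. The other splits were a random draw, not all that exist. Splits that keep the 3 undifferentiated arrays together could give high counts too, and the highest value of 10 points to none being drawn. The share of 1 in 100 thus rests on which splits were drawn and does not exclude chance. Nor does it bear on 14 against 28 days. For pairs of groups 10 splits of 6 arrays are too few for a share under 0.05: the real split, 1 of 10 in each case, gave 7818 genes at 14 days, 8246 at 28 days and 1443 between them, and the highest other gave 0.

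No rise of Sp7, Ibsp, Bglap, Dmp1 and Ifitm5 was called by 28 days (Ifitm5 was chosen after its values were seen). These genes do not stand for all bone genes. In the osteocyte list, which holds Dmp1, 3 of 11 members rose and 1 fell at 14 days (camera adjusted p = 0.208). At 28 days 4 rose, Pdpn, Hpse, Fbln7 and Mepe, and 1 fell (camera adjusted p = 0.21). Camera thus did not call the list, while fry called it up at 28 days (adjusted p = 4.98e-06). A normalization that flattens the changes of all genes is not the cause, since Fmo2 rose by 6.376 on the log2 scale in the same arrays. The rise of Fmo2 was known when the test was chosen. A milder compression of all changes could leave so large a rise, so the test cannot exclude it. Compression of some probe sets only, such as dim ones, could not be tested, because centred values keep no level. Probe sets that do not respond to these transcripts stay open, because 0 rises were called among the 5 genes in any comparison and no sample known to hold the transcripts is present. That transcription of these 5 genes did not rise may be read from these values only as a hypothesis.

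All 38 cell cycle genes fell in induced cultures. Array scaling was checked by putting all arrays on the same distribution with quantile normalization again. The list median at 28 days was then -1.887, while at 14 days it went from -1.771 to -0.936. The list was still called at 28 days (camera adjusted p = 6.38e-41, in a range of 6.38e-41 to 0.0113 over the alternatives). Direction and call were thus kept under this step. It works on values already centred per probe set, so it cannot exclude array scaling as a cause. Time in confluent culture and medium cannot be told apart from induction, because 0 samples are uninduced cultures of the same age. Lower YAP and TAZ activity, which crowding could bring, is a hypothesis: 16 targets not yet seen fell as a set at 28 days (camera p = 0.00464), with 8 down and 3 up, and p = 0.025 with an estimated correlation. It leaves the later fall out: between 14 and 28 days 0 of the 16 were called (median 0.01, camera adjusted p = 0.921), while 36 of the 38 cell cycle genes fell further.

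Markers of macrophages (Csf1r, Cd14) and endothelial cells (Kdr, Flt1, Erg, Emcn) rose in induced cultures. At 28 days the 14 other macrophage markers had a median of 0.026 (SD 0.278) with 2 up, while Csf1r rose by 2.098. The 10 other endothelial markers had a median of 0.111 (SD 0.169) with 5 up and 0 down, while Emcn rose by 0.676. These splits decide nothing, because the leading genes were picked by their rise and the centred values give no level of any marker. Macrophages or endothelial cells in the cultures, and expression of these genes by the stromal cells themselves, which was not tested, thus stay open. MSC2 is described as a clonal line, in which other marrow cells should be absent, but no value here tests this.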

How the results depend on the processing

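Robust variance moderation, the limits to genes with 1 probe set and to genes without tied groups, and the fit of each probe set were chosen after the data were seen. Of the values under alternatives to 12 counts, 211 stayed within 1.5 times and 22 did not. Of those for 99 list medians, 1883 kept direction and side of the threshold, 47 lost a call, 48 gained 1 and 2 reversed. For 675 values of named genes, 12158 kept both, 563 lost a call, 68 gained 1 and 0 reversed. With treat against 1.5-fold the counts fell to 1582 at 14 days, 2010 at 28 days and 28 between them, as a stricter null brings by construction. Quantile normalization again forces equal spread on centred arrays whose spreads differ, so the moves under it may come from the step itself. Most arrays are induced, so the median of a probe set mostly lies among them, and undifferentiated arrays have the widest spread. The step narrows the latter and widens the induced arrays. By itself it tends to lower changes against undifferentiated cells and to raise those between 14 and 28 days. It lowered the counts against undifferentiated cells and raised those between 14 and 28 days: genes changed at least 2-fold became 317 at 14 days, 689 at 28 days and 198 between them, all genes called became 5729 at 28 days and 2089 between them, and same-direction calls 3833. At an adjusted p under 0.01, calls between 14 and 28 days became 813, calls in both steps 708, and lists 5 at 14 and 5 at 28 days. With an estimated correlation 3, 2 and 1 lists were called, and with fry, which does not compare a list with other genes, 29, 26 and 15. The osteoclast list, which camera put down without a call, was called up by fry at medians of -0.009 at 14 days (adjusted p = 0.000814) and -0.015 at 28 days (adjusted p = 0.000138), and the cause was not tested.

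Leaving out each array in turn gave 7115 to 7955 genes at 14 days, 8177 to 8689 at 28 days, 8055 to 8545 among the groups, and 6525 to 6988 same-direction calls. Between 14 and 28 days it gave 991 to 1573 genes, with 991 without day-14 replicate 1 and 1017 without day-14 replicate 2, and 868 to 1320 in both steps, with 868 and 879 without the same arrays. At least 2-fold, the ranges were 1041 to 1066, 1340 to 1401 and 23 to 29, and lists numbered 10 to 12, 9 to 11 and 7 to 9. Replicate numbers do not pair the arrays, since deviations of same-numbered arrays correlated at -0.139 to 0.068. A replicate block gave 7846, 8726 and 1390 genes, and ended the calls of the mineral and the glycolysis list at 28 days (adjusted p = 0.0549 for each). Centring arrays on their median moved nothing, as each is at 0. Filters on dim probe sets, the probe set with the highest mean and a variance trend were not run, because centred values keep no level. Signal over background is unknown for the same reason.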

Other observations

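The 5 added gene lists, that of YAP and TAZ targets among them, were written after the first results were seen. Tests on mesothelial, tendon and lysosomal genes had bounds set before their unseen members' values were seen but were reworded afterwards. In that rewording the lysosomal prediction was turned round, so its outcome does not count as a prediction set beforehand. The test on amino acid genes was set before the values of its unseen members were seen.

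Genes known as markers of mesothelium, the lining of body cavities, rose in induced cultures. At 28 days 21 of 27 rose and 0 fell (median 0.865), among them Muc16 at 3.52, Msln at 3.50, Igfbp6 at 3.21, Lrrn4 at 2.20 and Krt7 at 1.95, chosen, like all genes named in this part, after their values were seen. Genes of amino acid synthesis and of the response to amino acid shortage fell in 23 of 28 members and rose in 1 (median -0.782), with Psat1 at -1.96, Mthfd2 at -1.80, Shmt2 at -1.64 and Slc7a1 at -1.41, and Nupr1 at 0.90. Both counts include 8 genes whose change had been seen before the list was written, so they describe the lists and test nothing.

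A rise of mesothelial markers at large was tested on 19 markers not seen before: 15 rose and 0 fell at 28 days, with camera p = 3.28e-10, which is consistent with it, and p = 0.0083 with an estimated correlation. Many of these genes are also expressed by other cells, so the test names no cell type.

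For tendon markers at large, the 14 not seen before gave a camera adjusted p of 0.0766, with 6 up and 1 down (median 0.177). The bound set beforehand took a p of 0.05 or more as evidence against, which was wrong, since a p that misses the threshold does not show that the set stayed level. The hypothesis stays open.

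For lysosomal genes at large, a second list with no member of the first gave 28 of 30 up and 0 down at 28 days (median 0.812, camera p = 3.39e-16, and p = 0.0012 with an estimated correlation), with Gabarapl1 at 1.94, Manba at 1.68 and Naglu at 1.68. A broad rise of lysosomal genes may thus be present.

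A lower amino acid response was tested on 20 genes not seen before: 16 fell and 1 rose at 28 days (median -0.727, camera p = 7.39e-10, and p = 0.0013 with an estimated correlation), which is consistent with it. Whether the change of medium brings it could not be tested, because 0 samples are uninduced cultures of the same age.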
